A study of Mus musculus with 6 samples.

How the data were processed

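Libraries were made from NK cells of mouse spleen cultured for 7 days with interleukin-2 at 20% or 1% oxygen and 5% CO2, 3 per group. Per the labels' protocols, RNA was extracted with a column kit and made into strand-specific mRNA libraries for DNBSEQ sequencing. Trim Galore 0.6.4, kallisto 0.4.6 and edgeR 3.17 are named in the submitters' processing notes, with the genome build GRCm39. Per the submitters' processing notes no order or setting of these tools is given, and the annotation release and the step from transcripts to genes are not given in the sources used here.

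The authors deposited 2 values per gene and library. The first of these deposited values is an estimated count per Ensembl gene for 56953 genes, made per the submitters' processing notes with kallisto among the tools and not normalized, of which 69.4% of values were whole numbers within a tolerance of 1e-06. The second, deposited as CPM, was on the log2 scale, from -4.80 to 14.0. It equalled the log2 CPM that edgeR computes from the deposited counts with a prior count of 2 and no composition factor (largest difference 0). Because kallisto divides reads between similar transcripts by likelihood, near-identical genes share counts, which affects granzymes, Ly49 receptors, mitochondrial genes with nuclear copies and ribosomal protein genes.

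Gene symbols came from a GENCODE M21 table, which pairs 52029 of the 56953 IDs with a symbol. IDs without a symbol held 0.32% to 0.40% of the counts per library. That annotation belongs to an earlier build than the authors' build, so it was used for names, GC content and transcript length, and no coordinates are given. List members were matched under the older symbol where the table holds it (Ero1l for Ero1a and the older ATP synthase symbols).

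Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15591 genes, and scaled with TMM. Hypoxia was compared with normoxia by the quasi-likelihood F-test of edgeR 4.0.16 without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were the absolute log2 fold change over the square root of F. Gene lists were tested with functions of limma 3.58.1, namely camera with an inter-gene correlation of 0.01, camera with an estimated correlation, and fry, over the 34 of 35 lists with at least 3 tested members. Of the lists, 10 were main lists of NK cell and hypoxia biology, 16 covered further processes and 9 held markers of other cell types.

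The genes named were set by a rule fixed before the data were examined, as were the lists, the main test and most other settings. The rule took the 6 largest increases and 6 largest decreases among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups, passing over gene models with a Gm number or a name ending in Rik. It added the 2 members with the smallest p from each main list, Hif1a, Vegfa, Ifng, Prf1, Gzmb, Klrk1 and Ncr1, up to 2 members of each further list that was called, and the 2 most abundant tested members of each cell-type list. Other named genes were chosen after their values were seen.

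Libraries of different groups share replicate numbers. The deviations of same-numbered libraries from their group means correlated across genes at 0.47, 0.33 and 0.30. All 6 libraries correlated best with their own number in the other group, so by a criterion of 0.1 the numbers were taken to pair the samples. Of the pairs with different numbers, hypoxia 2 and normoxia 3 also passed it (0.12), and the rest were negative. Deviations cancel within each group, so a difference of replicate 1 shared by both groups raises the correlations among replicates 2 and 3. The pairing comes from the replicate numbers in the labels together with these correlations. The main test has no block, and the replicate block is an alternative. Pairs of libraries of the same group differed by far more than sampling noise (mean chi-square per gene 12.4 to 61.3), so no library was counted as a repeated sequencing of another. This value cannot tell separate libraries of the same culture from separate cultures. The biological coefficient of variation was 10.9%, and 5.64% with the replicate block.

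Totals of 55104810 to 55794698 counts per library put 1 count at about 0.018 CPM, and a group with 0 counts was given a floor of 3 counts. The tests were tested on simulated data drawn from the means, dispersions and library sizes of the 15591 tested genes. For hypoxia against normoxia, 55.2% of genes changed 1.5-fold were recovered, 67.2% at 2-fold and 90.9% at 4-fold, with 8 of 15361 unchanged genes called. Only 230 genes were changed in the simulation, whereas 3261 were called in the data. The adjustment is stricter with fewer changed genes, so these shares may be too low for the data. Camera called 0 of 33 unchanged lists, in data simulated without correlation between genes.

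Other settings chosen before the data were examined were DESeq2 1.42.0 size factors, library size alone, the DESeq2 Wald test, limma-voom, no filter beyond a count above 0, a filter of at least 5 CPM in at least 3 libraries, the replicate block, leaving out each library, limma-trend on log2(CPM + 1), a fold change of at least 2 as well, and for lists the estimated correlation and fry. For limma-trend the deposited log2 values were first turned back into CPM. Added after the data were seen were leaving out both replicate 1 libraries, and an offset for GC content and transcript length (a lowess trend per library with a span of 0.3), with and without the replicate block. Genes that share sequence with mitochondrial or ribosomal protein genes were those with at least 10% of their 31-base words in common with them. All 6 libraries were used.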

Results

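The series asked how low oxygen affects mouse natural killer (NK) cells, lymphocytes that kill infected or malignant cells. Gene expression was measured in NK cells from the spleen of C57BL/6 mice after 7 days of culture with interleukin-2 (1700 U/ml), either at 20% oxygen (normoxia) or at 1% oxygen (hypoxia). Each group held 3 libraries that the labels call biological replicates. The labels do not say whether these came from separate mice, pools or cultures, so the p-values measure the spread between these 3 libraries per group. The total estimated count per library ran from 55104810 to 55794698, and 23933 to 26276 genes per library had a count above 0. At this depth 1 count was worth about 0.018 CPM (counts scaled to the library total). All levels below are CPM scaled with TMM, given as mean ± SD over n = 3 libraries, and all fold changes are hypoxia over normoxia on the log2 scale with their standard error (SE).

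The first principal component of log2 CPM held 55.5% of the variance and separated hypoxia from normoxia. The second held 22.0% and set the replicate 1 libraries of both groups (23.2 in hypoxia, 35.0 in normoxia) apart from the other 4 libraries, which lay between -20.2 and -11.4.

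**Figure D1:**
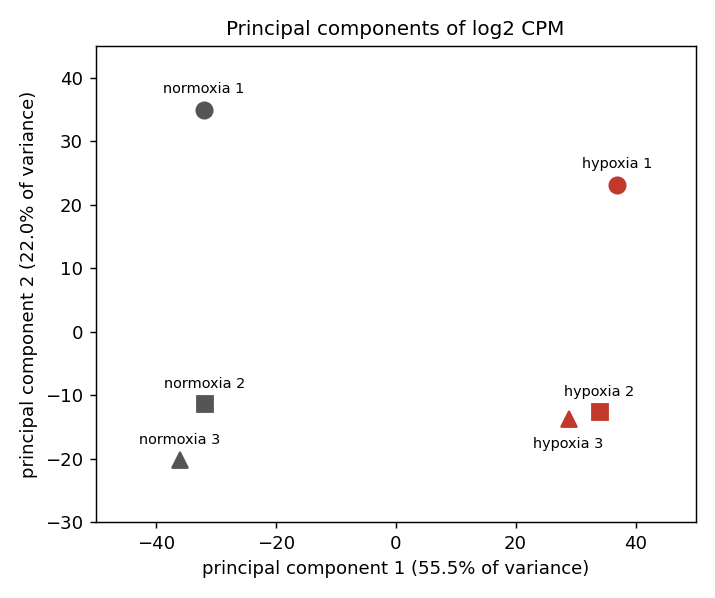
Principal components 1 and 2 of log2 CPM over the tested genes, with the share of variance on each axis; points are libraries, red for hypoxia and grey for normoxia, with a marker shape per replicate number. The 3 hypoxia libraries lie between 28.8 and 36.9 on component 1 and the 3 normoxia libraries between -36.0 and -31.8.

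After 7 days at 1% oxygen, the NK cell cultures held more mRNA of the integrin gene Itgae and less of the desaturase gene Scd1. The libraries do not tell which cells of the cultures carried these mRNAs. Of the listed genes, 27 of 31 interferon-stimulated genes, 18 of 22 amino acid response genes and 12 of 13 mitochondrially encoded mRNAs passed the test for single genes as lower. As lists these 3 were called lower by camera with a preset correlation but not with an estimated correlation (adjusted p = 0.28, 0.33 and 0.33). Itgae, which encodes the alpha E integrin CD103, rose 22.8-fold, from 0.871 ± 0.20 to 19.8 ± 2.87 CPM (log2 fold change 4.51, SE 0.18, edgeR adjusted p = 3.2e-06). Scd1, which encodes a stearoyl-CoA desaturase, fell 22.3-fold, from 272 ± 36.4 to 12.2 ± 3.59 CPM (log2 fold change -4.48, SE 0.21, edgeR adjusted p = 3.2e-06). Of 15591 genes tested, 1745 were higher and 1516 lower in hypoxia at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 656 and 298 of these changed at least 2-fold. Hypoxia and normoxia libraries did not overlap for 38.3% of the tested genes, where chance gives 10%.

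With the replicate number as a block in the fit (the replicate block), 2988 genes were higher and 3120 lower. Scaling by library size alone called 2384 higher and 998 lower, so the share of calls that were higher was 70.5% in place of 53.5%, and the median log2 fold change of all genes was 0.08 in place of -0.0052. Without hypoxia replicate 2 the calls were 1160 higher and 804 lower, and without normoxia replicate 2 they were 1146 and 942. Without both replicate 1 libraries, which stood apart, 1811 genes were higher and 1481 lower.

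Among called genes averaging at least 5 CPM whose groups did not overlap, the 6 largest increases were in Itgae, Gstm5, Tnfrsf23, Apln, Scin and Apol9b. Gstm5, a glutathione S-transferase gene, rose from 2.78 ± 0.626 to 12.9 ± 0.884 CPM, and Tnfrsf23, a receptor of the TNF receptor family, from 3.78 ± 0.473 to 16.8 ± 3.37 CPM. Apln, the gene of the peptide apelin, rose from 5.69 ± 1.34 to 23.3 ± 2.07 CPM. Scin, which encodes an actin-severing protein, rose from 117 ± 11.8 to 463 ± 41.6 CPM (log2 fold change 1.98, SE 0.10). Apol9b, from a family of near-identical genes between which the estimated counts may be shared, rose from 4.41 ± 0.0797 to 17.4 ± 0.883 CPM. The 6 largest decreases were in Ifi44, Scd1, Oasl1, Oasl2, Ifi27l2a and Usp18. Ifi44 fell from 9.94 ± 3.38 to 0.392 ± 0.117 CPM, Oasl1 from 10.4 ± 1.89 to 0.509 ± 0.0158 CPM and Oasl2 from 13.8 ± 3.51 to 1.22 ± 0.188 CPM. Ifi27l2a fell from 33.6 ± 6.29 to 3.47 ± 1.17 CPM, and Usp18, the gene of a protease that removes ISG15, from 16.4 ± 1.43 to 2.46 ± 0.280 CPM. The edgeR adjusted p of these 12 genes lay between 3.2e-06 and 3.0e-05.

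Gene lists were fixed before the data were examined and compared with all other genes by camera with a preset inter-gene correlation of 0.01. List members named below without a value were chosen after their values were seen. Of 34 lists tested, 8 were higher and 6 lower, and the 8 include the neutrophil markers, of which the 3 tested passed the filter through their counts in hypoxia alone. None of the 14 calls held with an inter-gene correlation estimated per list (lowest adjusted p = 0.28, 4 lists at an unadjusted p under 0.05). This correlation was estimated in the fit without the replicate block, so it includes differences shared by same-numbered libraries. It was not estimated with the block. Fry, which tests whether the genes of a list move on balance in a single direction, called 10 lists higher and 5 lower. With the block, fry called 0 lists (lowest adjusted p = 0.053). Other divisions of the same 6 libraries into 3 and 3 gave up to 14 lists past the threshold in a single direction. Each of these divisions had libraries of both oxygen levels on both sides, so they do not show how many lists pass without a difference.

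**Figure D2:**
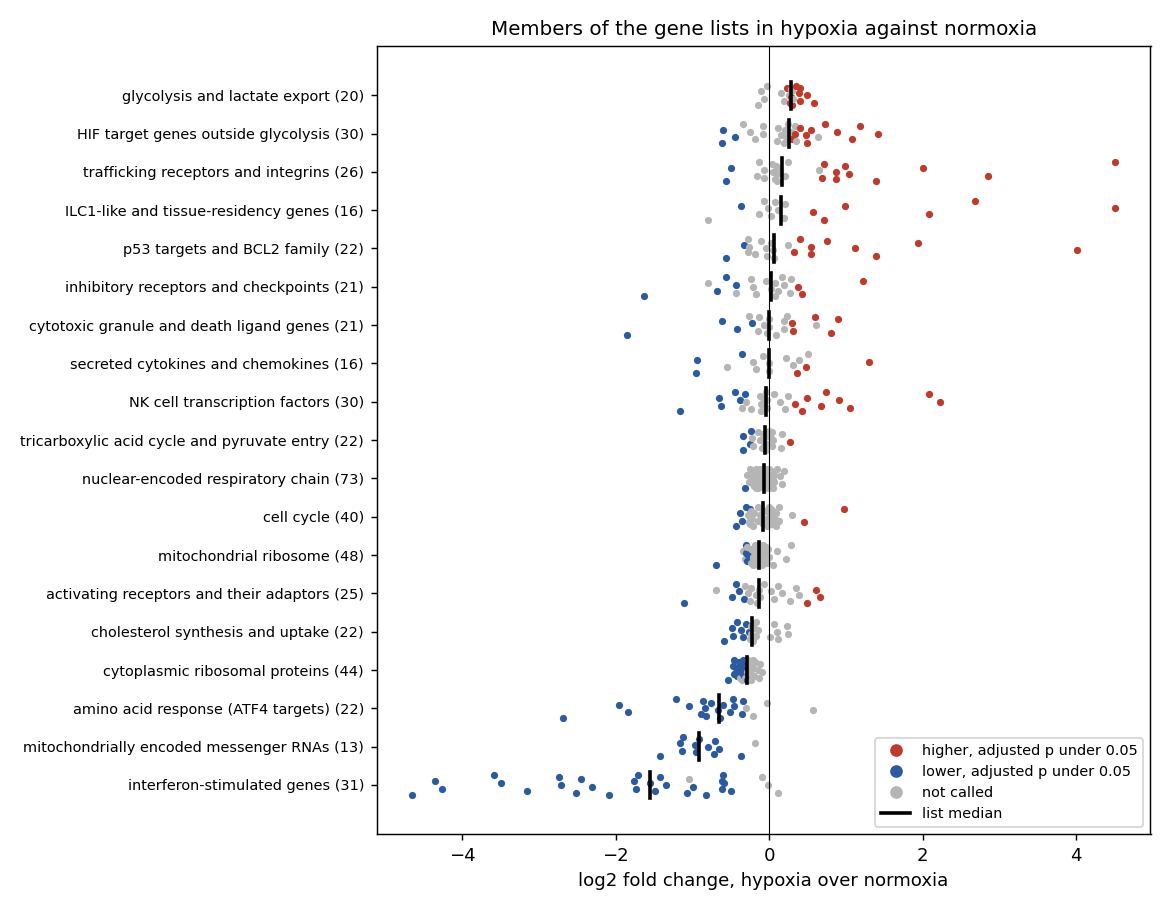
Log2 fold change (hypoxia over normoxia) of every tested member of the 10 main gene lists and of the further lists that camera called, with the number of tested members in brackets; points are genes, red or blue where the edgeR adjusted p was under 0.05, and the black bar is the list median. The medians run from -1.55 for the interferon-stimulated genes to 0.28 for glycolysis and lactate export.

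Genes that the transcription factor HIF is known to induce were called higher as a list by camera with the preset correlation. Neither an estimated correlation nor fry called them. Of 30 HIF target genes outside glycolysis, 11 rose and 3 fell, with a median log2 fold change of 0.26 (camera adjusted p = 0.00062). With an estimated correlation the adjusted p was 0.66, and fry gave 0.078. P4ha1, which encodes a subunit of collagen prolyl 4-hydroxylase, rose from 253 ± 13.4 to 534 ± 13.1 CPM (log2 fold change 1.08, SE 0.08, edgeR adjusted p = 2.4e-05), and Pfkfb3, the gene of a regulator of glycolytic flux, from 61.2 ± 6.66 to 112 ± 1.53 CPM (0.88, SE 0.09, edgeR adjusted p = 0.00013). The members that fell were Ddit4, Plin2 and Pfkfb4. Adjusted over the list alone, 12 rose and 4 fell, and with the replicate block 18 rose and 4 fell. Without normoxia replicate 1, 19 rose, and without both replicate 1 libraries 18 rose. Vegfa, the gene of a vascular growth factor, stood at 213 ± 9.97 CPM in hypoxia and 181 ± 16.4 CPM in normoxia, with an edgeR adjusted p of 0.076. It passed the threshold with the replicate block (edgeR adjusted p = 0.0088) and without normoxia replicate 1 (0.020), and also with scaling by library size (0.017), limma-trend (0.014), the stricter filter (0.046) and the offset for GC content and length (0.044).

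Of 20 genes of glycolysis and lactate export, 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 0.28 (camera adjusted p = 0.0015, and adjusted p = 0.65 with an estimated correlation). Pfkm, a phosphofructokinase gene, rose by a log2 fold change of 0.40 (SE 0.07) and Hk2, a hexokinase gene, by 0.50 (SE 0.09), with edgeR adjusted p of 0.0040 and 0.0042. With the replicate block or scaling by library size 16 rose, and with limma-trend 15. The count was 6, 6 and 5 without hypoxia replicates 1, 2 and 3, and 4 and 5 without normoxia replicates 2 and 3. Among 10 genes of oxygen sensing and the HIF subunits, 2 rose and 2 fell (3 and 4 adjusted over the list alone, 4 and 4 with the replicate block, 4 and 2 with scaling by library size and with limma-trend, camera adjusted p = 0.85). Arnt2 and Egln3 rose and Epas1 fell. Hif1a, the gene of the oxygen-regulated subunit HIF-1 alpha, fell from 135 ± 8.33 to 59.8 ± 2.36 CPM (log2 fold change -1.17, SE 0.07, edgeR adjusted p = 1.4e-05).

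Of 73 nuclear-encoded genes of the respiratory chain and ATP synthase, 1 fell and 0 rose (0 and 0 adjusted over the list alone, median -0.07, camera adjusted p = 0.098). The mitochondrially encoded subunits form a separate list, given below. With the replicate block 24 fell and 3 rose, and the list passed without hypoxia replicate 3 and without normoxia replicate 2 (camera adjusted p = 0.010 in both), with limma-voom (0.021) and with no filter on low counts (0.010). Its median was -0.12 without hypoxia replicate 3, -0.11 without normoxia replicate 2, -0.04 without hypoxia replicate 2, -0.03 without both replicate 1 libraries, and 0.01 with scaling by library size and with limma-trend. In these last 3 settings 2 rose and 1 fell. The member called was Uqcrq, a complex III subunit gene, at 63.8 ± 3.36 CPM in hypoxia and 79.1 ± 6.63 CPM in normoxia (edgeR adjusted p = 0.023). This call was lost without hypoxia replicate 1 (0.052), hypoxia replicate 2 (0.13) or normoxia replicate 3 (0.060) and without both replicate 1 libraries (0.0503), and 1 member rose without normoxia replicate 1. Ndufb4, a complex I subunit gene, had a log2 fold change of -0.25 (SE 0.09, edgeR adjusted p = 0.065, and 0.013 with the replicate block). Of 22 tricarboxylic acid cycle and pyruvate entry genes, 1 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.29), and with the replicate block 3 rose and 7 fell. With scaling by library size and with limma-trend 2 rose and 2 fell and the median was 0.02, against -0.06, and with DESeq2 size factors or no filter on low counts 0 rose. Dlat and Cs, which encode a pyruvate dehydrogenase subunit and citrate synthase, fell by 0.34 on the log2 scale (SE 0.08 for both). Without hypoxia replicate 2 their log2 fold changes were -0.27 and -0.29 and no longer passed (edgeR adjusted p = 0.099 and 0.10), and without hypoxia replicate 3 that of Cs was -0.33 (edgeR adjusted p = 0.061). No cycle gene was called without hypoxia replicate 2 (0 rose and 0 fell with edgeR), and 2 fell without hypoxia replicates 1 or 3 or normoxia replicates 2 or 3. With single libraries left out, 1 rose without normoxia replicate 3 and 0 without each of the other 5. Pdhb and Idh3g also fell and Dlst rose.

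Of the 13 mitochondrially encoded mRNAs, 12 fell and 0 rose, also adjusted over the list alone, with a median log2 fold change of -0.92 (camera adjusted p = 4.3e-12, and adjusted p = 0.33 with an estimated correlation). mt-Co3, a cytochrome c oxidase subunit, fell from 2014 ± 66.2 to 1067 ± 74.2 CPM, and mt-Nd4l, a complex I subunit, from 184 ± 35.7 to 82.3 ± 3.92 CPM (edgeR adjusted p = 7.9e-05 and 0.00030). These genes share sequence with nuclear copies, so their estimated counts are uncertain taken singly. Of 48 genes of the mitochondrial ribosome, 5 fell and 0 rose (3 and 0 adjusted over the list alone, median -0.14, camera adjusted p = 0.0077). With an estimated correlation the adjusted p was 0.82, the list did not pass without normoxia replicate 3 (0.13, median -0.07), with the stricter filter (0.061) or with fry (0.16), and with the replicate block 20 fell and 2 rose. Members that fell numbered 3 without hypoxia replicate 1 and 1 without hypoxia replicate 2, and 1 rose without normoxia replicates 1 or 3. Scaling by library size and limma-trend each gave 2 higher and 1 lower, with medians of -0.06 and -0.05, the DESeq2 Wald test gave 8 lower, and without both replicate 1 libraries 1 rose and 3 fell. Mrpl38 fell from 28.7 ± 2.12 to 17.8 ± 0.835 CPM.

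Cytotoxic genes moved in both directions. Of 21 cytotoxic granule and death ligand genes, 5 rose and 4 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.87), and with the replicate block 9 rose and 5 fell. Without hypoxia replicates 1 or 2, 2 and 3 rose, and without normoxia replicates 2 or 3, 2 rose. Gzmf, a granzyme gene, fell from 513 ± 129 to 143 ± 38.2 CPM (log2 fold change -1.85, SE 0.21, edgeR adjusted p = 0.00035). Its near relatives Gzmc, Gzmd, Gzme and Gzmg, with which reads may be shared, were not called, with log2 fold changes of 0.09, -0.13, 0.0032 and -0.14. Ctsw, Lamp1, Gzmk and Ctsc also rose, and Fasl and Unc13d fell. Stx11, which encodes a syntaxin of granule release, fell from 36.3 ± 2.24 to 23.6 ± 0.733 CPM (edgeR adjusted p = 0.00050). Gzma, the gene of granzyme A, chosen after its values were seen, rose from 5684 ± 723 to 9931 ± 730 CPM (edgeR adjusted p = 0.00071). Gzmb, the gene of granzyme B, stood at 11744 ± 1432 CPM in hypoxia and 11992 ± 697 CPM in normoxia, a difference smaller than the SD of either group (edgeR adjusted p = 0.87). Prf1, the perforin gene, stood at 1983 ± 156 and 2387 ± 106 CPM (log2 fold change -0.27, SE 0.08), with an edgeR adjusted p of 0.051. It was 0.0055 with the replicate block and 0.040 without hypoxia replicate 3, and 0.046, 0.012 and 0.048 with DESeq2 size factors, the DESeq2 Wald test and limma-voom.

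Of 16 secreted cytokine and chemokine genes, 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.95), and with the replicate block 5 rose and 4 fell. Without normoxia replicate 2, 1 fell. Tnfsf11, the gene of RANKL, fell from 14.6 ± 0.496 to 7.60 ± 1.39 CPM, and Flt3l, the gene of the FLT3 ligand, rose from 88.8 ± 2.56 to 124 ± 4.71 CPM (edgeR adjusted p = 0.00081 and 0.0011). Ccl5 and Ccl3 also rose, and Csf2 and Ltb fell. Ifng, the interferon gamma gene, stood at 52.6 ± 7.67 CPM in hypoxia and 52.5 ± 1.24 CPM in normoxia (edgeR adjusted p = 0.99).

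Receptor genes were also split. Of 25 activating receptor and adaptor genes, 3 rose and 5 fell (5 and 8 adjusted over the list alone, median -0.14, camera adjusted p = 0.29), and with the replicate block 5 rose and 10 fell. Without hypoxia replicate 2, 2 fell, and without normoxia replicate 1, 5 rose and the median was -0.03. It was -0.07 without both replicate 1 libraries (5 higher and 6 lower) and -0.06 with scaling by library size and with limma-trend (5 and 4 in each), and the DESeq2 Wald test gave 5 and 6 and no filter 4 and 8. Cd2, an adhesion and costimulatory receptor gene, fell from 24.1 ± 0.420 to 11.1 ± 0.835 CPM (edgeR adjusted p = 3.0e-05), and Cd226, the gene of DNAM-1, rose (log2 fold change 0.61, SE 0.09, edgeR adjusted p = 0.0011). Hcst and Cd27 also rose, and Cd247, Klra4, Klrb1a and Tnfrsf18 fell, of which Klra4 has near-identical relatives. Klrk1, the gene of NKG2D, had a log2 fold change of -0.28 (SE 0.10, edgeR adjusted p = 0.072), and Ncr1, the gene of NKp46, a log2 fold change of -0.23 (SE 0.08, edgeR adjusted p = 0.081). Both passed with the replicate block (0.0026 and 0.0049), and Klrk1 also passed without hypoxia replicate 3 (0.022), with the DESeq2 Wald test (0.030) and with no filter on low counts (0.033). Of 21 inhibitory receptor and checkpoint genes, 3 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.79), and with the replicate block 5 rose and 8 fell. Without hypoxia replicate 1 or normoxia replicates 2 or 3, 1 rose, and without normoxia replicate 1, 5 rose. With scaling by library size and with limma-trend 5 rose, and without both replicate 1 libraries 6 rose. Nt5e, the gene of the ectoenzyme CD73, rose from 19.6 ± 1.92 to 45.6 ± 2.86 CPM, and Klrg1, an inhibitory lectin-like receptor gene, fell from 42.5 ± 12.2 to 13.7 ± 2.77 CPM (edgeR adjusted p = 3.0e-05 and 0.00047). Cd96 and Lag3 also rose, and Havcr2, Klra5 and Klra1 fell.

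**Figure D3:**
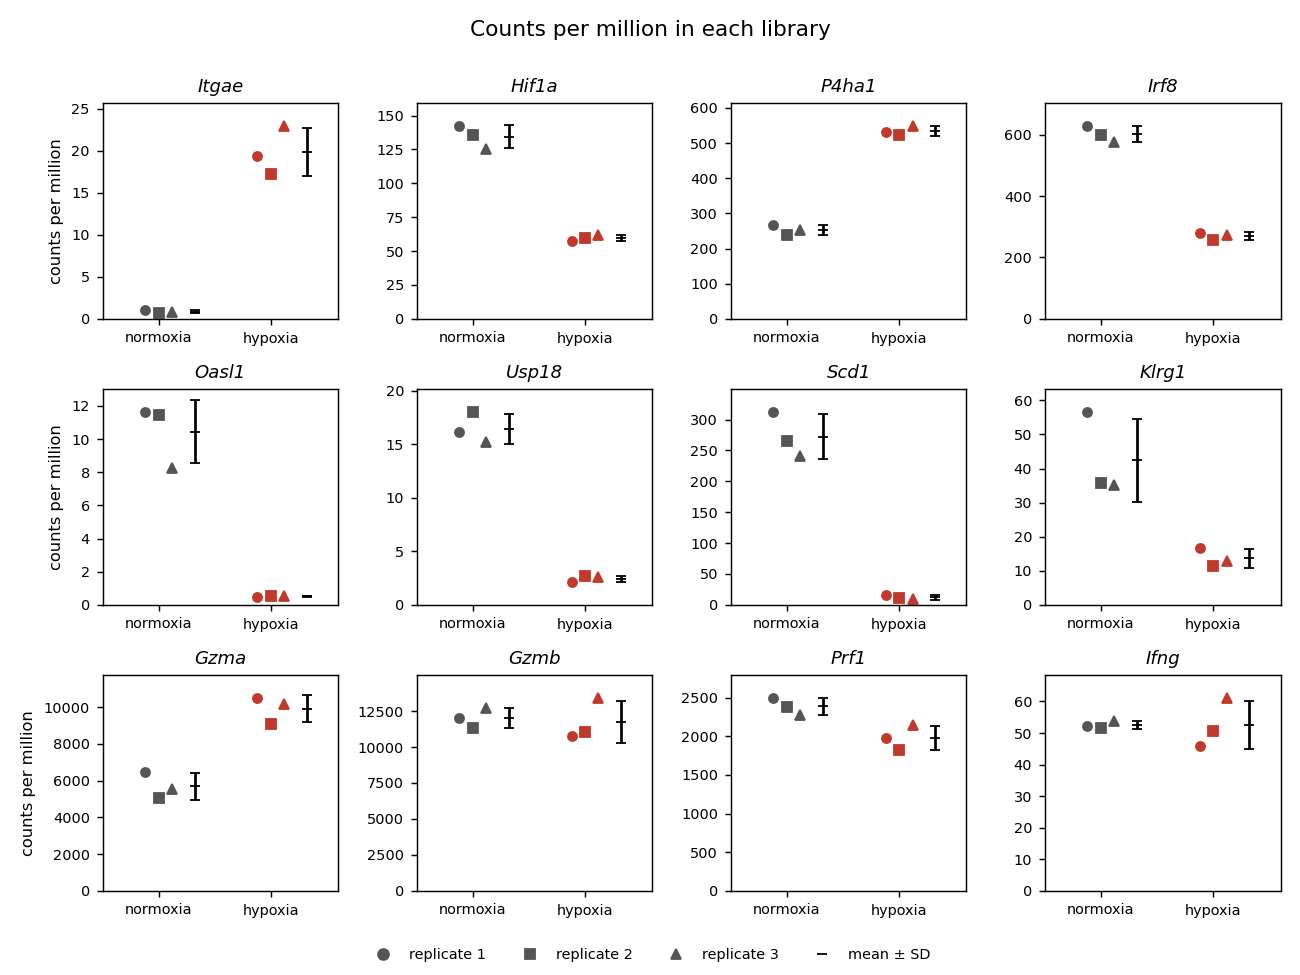
CPM (linear axes from 0, a scale per panel) of 12 genes in every library, grey for normoxia and red for hypoxia, with a marker shape per replicate number and the mean ± SD beside each group. All 3 hypoxia libraries lie above all 3 normoxia libraries for Itgae, P4ha1 and Gzma, and below them for Hif1a, Irf8, Oasl1, Usp18, Scd1, Klrg1 and Prf1, while the groups overlap for Gzmb and Ifng; the edgeR adjusted p of Prf1 was 0.051.

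Of 30 transcription factor genes of NK cells, 9 rose and 6 fell (10 and 6 adjusted over the list alone, camera adjusted p = 0.40), and 3 fell without hypoxia replicate 2 or normoxia replicate 2. Irf8, an interferon regulatory factor gene, fell from 601 ± 25.4 to 269 ± 12.4 CPM (log2 fold change -1.16, SE 0.08, edgeR adjusted p = 1.7e-05), and Zfp683, the gene of the residency factor Hobit, rose from 0.874 ± 0.0184 to 3.69 ± 0.254 CPM (2.08, SE 0.16, edgeR adjusted p = 3.0e-05). The trafficking and residency lists, which share Itgae, Itga1, Cxcr6 and Cd69, were called higher with the preset correlation but not with an estimated correlation. Their mean log2 fold changes, 0.62 and 0.67, lay above their medians, and Itgae had the largest in both. Of 26 trafficking receptor and integrin genes, 10 rose and 2 fell, also adjusted over the list alone (median 0.16, camera adjusted p = 1.7e-06, and adjusted p = 0.35 with an estimated correlation). Without any of the 3 hypoxia libraries or normoxia replicates 1 or 2, 1 fell, also without both replicate 1 libraries and with limma-trend, and with the stricter filter 6 of 21 rose. After Itgae, the member with the smallest p was Itgax, the gene of the integrin CD11c, which rose from 180 ± 12.5 to 328 ± 22.1 CPM (edgeR adjusted p = 0.00015). Of 16 ILC1-like and tissue-residency genes, led by Itgae and Zfp683, 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.16, camera adjusted p = 1.6e-06, and adjusted p = 0.33 with an estimated correlation). With the replicate block or without normoxia replicate 3, 2 fell, and without hypoxia replicate 2, 0 fell. The median was 0.08 without normoxia replicate 3, 0.25 without both replicate 1 libraries and 0.24 with scaling by library size, which also moved that of the trafficking list to 0.25. Some markers of other cells rose in the same libraries, among them Mcpt8 of the basophil list (log2 fold change 1.91) and Cd68 of the monocyte list (1.91). Others fell, namely 1 of 6 monocyte markers and 4 of 7 dendritic cell markers, against 2 higher in each of these lists.

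Cell cycle genes did not pass as a list. Of 40 members, 2 rose and 5 fell, also adjusted over the list alone (median -0.08, camera adjusted p = 0.29), and with the replicate block 3 rose and 15 fell. With scaling by library size and with limma-trend the median was 0.0056 and 0.01 and 2 fell, and with the DESeq2 Wald test 9 fell. Without hypoxia replicates 2 or 3, 2 fell, without normoxia replicate 2, 3 fell, and without normoxia replicate 3, 4 rose. Ccne2, the gene of cyclin E2, rose from 31.6 ± 6.95 to 62.2 ± 5.11 CPM, and E2f1, a gene of an S-phase transcription factor, from 48.8 ± 5.29 to 66.5 ± 2.56 CPM (edgeR adjusted p = 0.0011 and 0.0055). Those that fell were Bub1b, Cenpe, Cdc20, Aurkb and Tyms. Of 22 p53 target and BCL2 family genes, 9 rose and 2 fell (9 and 3 adjusted over the list alone, median 0.06, camera adjusted p = 0.00062, and adjusted p = 0.33 with an estimated correlation). The mean log2 fold change of this list, 0.42, lay above its median, and Eda2r had the largest. With the replicate block 4 fell, without hypoxia replicates 1 or 2, 0 fell, and without normoxia replicate 2, 1 fell. The median was 0.0099 without normoxia replicate 3, 0.12 without normoxia replicate 1, 0.09 without hypoxia replicate 3, 0.12 without both replicate 1 libraries and 0.14 with scaling by library size and with limma-trend, where the list did not pass with limma-trend (camera adjusted p = 0.060) and 1 fell in both. Phlda3, a p53 target gene, rose from 4.56 ± 0.575 to 17.4 ± 1.06 CPM (log2 fold change 1.94, SE 0.11, edgeR adjusted p = 1.1e-05), and Eda2r, a receptor gene, from 0.0370 ± 0.000993 to 0.632 ± 0.0583 CPM (4.02, SE 0.36, edgeR adjusted p = 8.4e-05). At about 0.018 CPM per count, Eda2r had only a few counts in each normoxia library and passed the filter through hypoxia alone. Its normoxia SD and the size of its change are therefore poorly measured.

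Interferon-stimulated genes showed the lowest list median. Of 31 tested, 27 fell and 0 rose, also adjusted over the list alone, with a median log2 fold change of -1.55 (camera adjusted p = 7.2e-71). With an estimated correlation the adjusted p was 0.28, and fry gave 0.0048. Oasl1 fell by 4.35 on the log2 scale (SE 0.19) and Usp18 fell by 2.74 (SE 0.12), with an edgeR adjusted p of 3.2e-06 for both.

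Of 22 amino acid response and serine one-carbon genes, targets of the transcription factor ATF4, 18 fell and 0 rose (19 and 1 adjusted over the list alone), with a median log2 fold change of -0.66 (camera adjusted p = 2.0e-13, and adjusted p = 0.33 with an estimated correlation). With the replicate block, without normoxia replicate 1, without both replicate 1 libraries, with scaling by library size, either other filter, limma-voom, limma-trend or the DESeq2 Wald test, 1 rose. Mthfd2, a gene of mitochondrial folate metabolism, fell from 142 ± 10.6 to 83.7 ± 1.32 CPM, and Nupr1, a stress-response gene, from 2.09 ± 0.333 to 0.321 ± 0.0325 CPM (edgeR adjusted p = 0.00016 and 5.2e-05). Of 22 genes of cholesterol synthesis and uptake, 8 fell and 0 rose (9 and 0 adjusted over the list alone, median -0.22, camera adjusted p = 0.0040). An estimated correlation gave an adjusted p of 0.68 and fry gave 0.058, and with scaling by library size and with limma-trend the median was -0.14 and 2 rose. Without hypoxia replicate 2 the camera adjusted p was 0.054 and 4 fell, without normoxia replicate 1, 1 rose, and with the replicate block 16 fell and 2 rose. Pmvk and Fdps, genes of the mevalonate pathway, fell by 0.60 and 0.49 on the log2 scale (SE 0.08 and 0.09). Of 44 cytoplasmic ribosomal protein genes, 22 fell and 0 rose (33 and 0 adjusted over the list alone, 41 and 0 with the replicate block), with a median log2 fold change of -0.29 (camera adjusted p = 2.6e-09, and adjusted p = 0.60 with an estimated correlation). Without hypoxia replicates 1 or 2, 11 and 7 fell, and without normoxia replicate 3, 14 fell, as did 13 with limma-trend. Rps20 fell by 0.54 and Rpl10a fell by 0.46 on the log2 scale (SE 0.08 and 0.07), and reads of such genes can be shared with their pseudogenes.

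The other lists of cell state did not pass with camera, and fry called the angiogenic and matrix factors higher (adjusted p = 0.040). Of 19 fatty acid oxidation genes, 2 rose and 1 fell (camera adjusted p = 0.95), and of 17 endoplasmic reticulum chaperone genes, 2 rose and 1 fell (0.55). Of 27 cytokine receptor and feedback genes, 6 rose and 4 fell (0.57), of 14 angiogenic and matrix factor genes, 4 rose and 0 fell (0.19), of 19 genes of 2-oxoglutarate-dependent demethylases, 3 rose and 1 fell (0.57), and of 21 immediate early and heat shock genes, 4 rose and 2 fell (0.72). Adjusted over the list alone, the counts of these 6 lists were the same except that 5 cytokine receptor genes fell. With the replicate block 7 angiogenic genes rose and 2 fell, 5 chaperone genes rose, 8 cytokine receptor genes fell, 6 demethylase genes rose and 6 fell, 9 immediate early genes rose and 7 fell, and 2 fatty acid oxidation genes fell. With scaling by library size and with limma-trend 4 chaperone genes rose, 5 demethylase genes rose and 0 fell (edgeR and limma), 6 angiogenic genes rose and 6 immediate early genes rose, and without both replicate 1 libraries 7 immediate early genes rose. With single libraries left out, these counts of up to 6 genes ranged from 1 to 2 higher and 0 to 1 lower for fatty acid oxidation, 0 to 2 and 1 for chaperones, 5 to 6 and 2 to 4 for cytokine receptors, 1 to 5 and 0 for angiogenic factors, 3 to 4 and 0 to 1 for demethylases and 3 to 9 and 2 to 3 for immediate early genes. The lowest angiogenic count, 1, came without hypoxia replicates 2 or 3 or normoxia replicate 2, and the highest immediate early count, 9, without normoxia replicate 1. No chaperone gene rose without hypoxia replicates 2 or 3 or normoxia replicate 2 (0 with edgeR), and 2 cytokine receptor genes fell without hypoxia replicate 2 or normoxia replicate 2. No demethylase gene fell without any single library except normoxia replicate 1 (0 with edgeR), and 1 fatty acid oxidation gene rose without hypoxia replicates 1 or 3 or normoxia replicates 2 or 3, with 0 lower without normoxia replicate 2. Median and mean had opposite signs for the inhibitory receptors (0.03 and -0.09), the transcription factors (-0.04 and 0.15), the secreted cytokines (-0.0026 and 0.02) and the monocyte markers (-0.05 and 1.16). These medians changed sign with single libraries left out, namely for the inhibitory receptors without hypoxia replicate 3 or normoxia replicate 3 (-0.03 in both), for the transcription factors without hypoxia replicate 1 or normoxia replicate 1 (0.00035 and 0.0089), for the cytokines without hypoxia replicates 1 or 2 or normoxia replicate 3 (0.12, 0.0054 and 0.11), and for the monocyte markers without hypoxia replicate 3 or normoxia replicate 1 (0.0058 and 0.03). Over all 6 libraries left out in turn these medians ran from -0.03 to 0.13, -0.07 to 0.0089, -0.11 to 0.12 and -0.14 to 0.03, and with scaling by library size they were 0.11, 0.05, 0.08 and 0.04.

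Of the marker lists of other cell types, those of B cells, neutrophils and mast cells passed as higher with the preset correlation and none with an estimated correlation. The libraries do not tell whether other cells or the NK cells carried these transcripts. Single genes made up most of some lists. In hypoxia Ighm held 73.8 of 77.4 CPM of the tested B cell markers, and Pecam1 held 202 of 203 CPM of the tested stromal markers. Of 15 T cell markers, 4 rose and 0 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.086, 0.0042 without hypoxia replicate 1 and 0.010 with no filter on low counts), and with the replicate block 6 rose and 2 fell. Cd3d, Cd3g, Cd4 and Bcl11b rose. The most abundant were the T cell receptor constant genes Trbc1, at 293 ± 16.8 CPM in hypoxia and 333 ± 17.9 CPM in normoxia, and Trbc2, at 104 ± 5.54 and 122 ± 7.73 CPM. Neither was called (edgeR adjusted p = 0.14 and 0.066) but both were lower with the replicate block (0.010 and 0.0083), and Trbc2 with the DESeq2 Wald test (0.042). Of 3 tested B and plasma cell markers, 2 rose (3 adjusted over the list alone, camera adjusted p = 0.0040, and 0.33 with an estimated correlation). With no filter on low counts 14 could be tested, of which 3 rose, and the list did not pass (median 0.09, camera adjusted p = 0.23). Ighm, an immunoglobulin heavy chain gene, stood at 73.8 ± 2.64 and 60.8 ± 7.92 CPM (edgeR adjusted p = 0.061, 0.0022 with the replicate block and 0.0051 without normoxia replicate 1, and between 0.013 and 0.042 with scaling by library size, limma-trend, either other filter or the GC and length offset), and Ighd rose from 1.10 ± 0.252 to 2.61 ± 0.162 CPM. Of 6 monocyte and macrophage markers, 2 rose and 1 fell (2 with the replicate block), also adjusted over the list alone (camera adjusted p = 0.57, fry adjusted p = 0.040). Cd68 rose from 16.4 ± 6.15 to 61.9 ± 16.5 CPM, and Ctss stood at 19.3 ± 2.67 CPM in hypoxia and 20.0 ± 0.281 CPM in normoxia. Of 7 dendritic cell markers, 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.10, 0.047 without hypoxia replicate 3 and 0.043 with no filter on low counts, and fry adjusted p = 0.028). Without hypoxia replicates 2 or 3 or normoxia replicates 2 or 3, 1 rose. Those that fell included Bst2, which the interferon list also holds and which fell from 42.4 ± 3.78 to 21.3 ± 2.23 CPM. The class II gene H2-Ab1 rose from 23.4 ± 5.08 to 38.5 ± 1.89 CPM, while H2-Aa and H2-Eb1 fell.

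Of 4 mast cell and basophil markers, 2 rose and 0 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.019, and adjusted p = 0.60 with an estimated correlation). Without normoxia replicate 2 the adjusted p was 0.088 and the median -0.01, against 0.69 with all libraries, 1.14 without hypoxia replicate 1 and 0.36 without normoxia replicate 1. The list did not pass with limma-voom (0.22) or limma-trend (0.43). Without hypoxia replicate 1 or normoxia replicates 2 or 3, 1 rose, and with the replicate block 1 also fell. Mcpt8, a mast cell protease gene, rose from 21.2 ± 4.10 to 79.7 ± 6.61 CPM (edgeR adjusted p = 1.9e-05). Cpa3 rose from 0.704 ± 0.498 to 1.96 ± 0.471 CPM (log2 fold change 1.49, edgeR adjusted p = 0.027). Its log2 fold change was 1.27, 1.26 and 1.17 without hypoxia replicate 1, normoxia replicate 2 or normoxia replicate 3, and no longer passed (edgeR adjusted p = 0.078, 0.10 and 0.069). Of 11 neutrophil markers 3 had enough counts to be tested, at trace levels. These had at most 1 count each in normoxia and passed the filter through hypoxia alone, so their list test (3 higher, also adjusted over the list alone, camera adjusted p = 3.8e-05, and 0.33 with an estimated correlation) says nothing of the other members. With no filter on low counts 10 could be tested, of which 5 rose and 0 fell (edgeR, median 2.54, camera adjusted p = 3.9e-05, and 0.29 with an estimated correlation). Ly6g, not tested with the filter, had 5 counts in hypoxia and 19 in normoxia. Ngp had 47, 44 and 25 counts in the hypoxia libraries and 0 in all 3 normoxia libraries. Against a floor of 3 counts over the normoxia group it was at least 36.7-fold higher. S100a9 had 74 counts in hypoxia and 1 in normoxia, a ratio of 70.3 with an exact 95% interval from 12.2 to 2814 that covers counting error only. With Ngp at its bound, the median log2 fold change of the 3 markers was 5.65. Of 7 ILC2 and ILC3 markers, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.099, 0.012 with no filter on low counts, and fry adjusted p = 0.0023). Rora rose from 13.9 ± 0.743 to 25.8 ± 5.65 CPM and Calca fell by 0.72 on the log2 scale (SE 0.15). Of 4 stromal and endothelial markers, 0 rose and 1 fell (1 and 1 adjusted over the list alone and with the replicate block, camera adjusted p = 0.85). Pecam1, at 202 ± 9.33 CPM in hypoxia and 257 ± 23.7 CPM in normoxia (edgeR adjusted p = 0.019), was not called without hypoxia replicate 2 (0.10) or normoxia replicate 2 (0.061), while 1 other marker rose without normoxia replicate 2. Col1a2 stood at 0.537 ± 0.226 and 0.381 ± 0.136 CPM. The erythroid and platelet list had 1 tested member and was not tested as a list with the filter (camera adjusted p = 0.17 with no filter, where 2 of 11 rose). This member, Itga2b, stood at 1.43 ± 0.195 and 1.13 ± 0.213 CPM and was not called (edgeR adjusted p = 0.29).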

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

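Leaving out both replicate 1 libraries and the offset for GC content and transcript length, with or without the replicate block, and no filter together with an estimated correlation for the neutrophil markers, were chosen after the data were seen. Against 1745 genes higher and 1516 lower, the replicate block gave 2988 and 3120, the block with the GC and length offset 3242 and 2920, the stricter filter 1123 and 1005, and a fold change of at least 2 as well 656 and 298. The last of these follow from fewer genes tested and a second criterion. Library size alone gave 998 lower and limma-trend 988 lower, with a median log2 fold change of all genes of 0.08 and 0.06. With single libraries left out, 1146 to 1980 genes were higher and 804 to 1636 lower. No gene called in the main comparison was called in the opposite direction or had the opposite sign in any of these settings (0 of 3261). Of 8 lists higher and 6 lower, the stricter filter left 5 higher (11 of the 14 could still be tested), the estimated correlation 0 and 0, and leaving out single libraries 7 to 9 and 5 to 8. No list call or named-gene call was lost with the replicate block, which added 8 named genes, all given in the report; fry with the block called 0 lists (lowest adjusted p = 0.053). Besides all 14 with the estimated correlation, and those lost without a single library that the report gives, lists lost were the mitochondrial ribosome with the stricter filter (camera adjusted p = 0.061) and fry (0.16), HIF targets and cholesterol synthesis with fry (0.078 and 0.058), p53 targets with limma-trend (0.060), B cell markers without a filter (0.23), and mast cell markers with limma-voom (0.22) and limma-trend (0.43). Lists gained were the nuclear-encoded respiratory chain with limma-voom (0.021) and without a filter (0.010), T cell markers without a filter (0.010) and without both replicate 1 libraries (0.0034), dendritic cell markers and ILC2 and ILC3 markers without a filter (0.043 and 0.012) and with fry (0.028 and 0.0023), and angiogenic factors and monocyte markers with fry (0.040 for both). Except for the filters and the added criterion, the cause was not tested. In simulated data 55.2% of genes changed 1.5-fold were recovered, so small changes can be missed. That simulation changed only 230 genes, far fewer than the 3261 called here, so the share in the data may be higher.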

Other observations

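The fatty acid list, the markers of other cells, the nuclear copies and the mitochondrial ribosomal RNAs below were tested only after the results were seen. Scd1 was among the largest decreases, and Fads2, another desaturase gene, fell from 269 ± 14.7 to 60.4 ± 9.05 CPM. In an added list of fatty acid synthesis and desaturation genes, 9 of the 17 other tested genes fell and 0 rose (edgeR, 12 lower with the replicate block), with a median log2 fold change of -0.59. Camera gave an unadjusted p of 3.4e-17 with the preset correlation and 0.0068 with an estimated correlation. Scd2 fell from 2387 ± 111 to 850.5 ± 75.0 CPM, and Acsl3, Fads1, Fads3, Elovl6, Srebf1, Acaca, Acss2 and Mid1ip1 also fell. Fasn, at 422 ± 25.4 CPM in hypoxia and 510.3 ± 76.1 CPM in normoxia, was not called (edgeR adjusted p = 0.11) but was lower with the replicate block (0.0042), without normoxia replicate 1 (0.0092), without both replicate 1 libraries (0.014) and with no filter on low counts (0.046). Hsd17b12 and Elovl1 were also lower with the block (0.0026 and 0.00078), Elovl1 also without both replicate 1 libraries (0.030) and with no filter (0.040), and Acly was called neither without nor with it (0.63 and 0.35). A hypothesis from these data is that desaturation and fatty acid synthesis genes may have fallen as a group, which the 9 further genes fit, though list and test came from the same data.

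Of the interferon-stimulated genes 27 fell, with a median log2 fold change of -1.55. With the GC and length offset 27 fell, and 28 with the replicate block, with or without the offset (median -1.54 with both), and at least 27 fell whichever library was left out, which argues against GC or length bias or a single library as the whole cause. Loss of other cells that carried these transcripts cannot be told apart from a change in the NK cells. Without Bst2, a dendritic cell marker that the interferon list also holds, markers of 6 other cell types summed to 166.9 CPM in normoxia and 297.7 CPM in hypoxia, most of the difference in Cd68 and Mcpt8, and each type's sum was higher, while with Bst2 the 7 tested dendritic cell markers summed to 78.2 and 68.6 CPM and 4 of them fell. Again without Bst2, the markers that were lower lost 8.61 CPM, or 1.78% of the 485 CPM lost by the interferon genes, which 166.9 CPM could not have reached, and marker levels do not limit what interferon-gene RNA such cells carried, so this stays open beside a lower interferon response of the NK cells at 1% oxygen, which may also account for the pattern.

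Of 13 mitochondrially encoded mRNAs 12 fell, also with the GC and length offset, with the replicate block and with both (12 in each, median -0.88 with both). Summed with the 13 genes that share their sequence they were lower by a log2 ratio of -0.80, with all hypoxia libraries below all normoxia libraries, which argues against reads moved between these genes. Both mitochondrial ribosomal RNAs rose (mt-Rnr1 by 1.09, mt-Rnr2 by 0.43 on the log2 scale), which argues against a loss of mitochondrial RNA of every kind, although libraries selected for mRNA may catch ribosomal RNA unevenly. A difference in mRNA level at 1% oxygen stays open as a hypothesis.

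Of 44 ribosomal protein genes 22 fell, 20 with the GC and length offset, 41 with the replicate block and 41 with both (median -0.27), so the higher count came with the block. Summed with 397 genes that share their sequence they had a log2 ratio of -0.31, and the highest median over TMM, median-of-ratios and library-size scaling was -0.21. These values argue against GC or length bias, shared reads and scaling as the whole cause, and a lower share of ribosomal protein mRNA at 1% oxygen may be a hypothesis to follow up.

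The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 1745 genes higher and 1516 lower with edgeR, and was 1 of 10 with as many in each case, where the highest other gave 0 (29 to 1095 genes at an unadjusted p under 0.05, against 5244). Every other division had libraries of both oxygen levels on each side. The oxygen difference then added to the spread within groups, so the counts of genes and lists there are no measure of chance. Of the 4 divisions that part all 3 pairs of same-numbered libraries, the other 3 also called 0 genes with the replicate block, and the remaining 6 part 1 pair. For lists, 5 of 10 divisions called as many as the 8 lists higher in a single direction and 7 of 10 as many as the 6 lower, with 14 as the highest of the others. In either direction together the real division called 14 lists and the highest of the others 19.

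Xist stood at 279 ± 41.9 CPM in hypoxia and 290 ± 26.6 CPM in normoxia, with an edgeR adjusted p of 0.79. Of 4 Y-linked genes Uty fell, from 12.1 ± 0.184 to 8.26 ± 1.53 CPM (log2 fold change -0.55, edgeR adjusted p = 0.015, 0.0012 with the replicate block and 0.053 without hypoxia replicate 2). Ddx3y stood at 42.2 ± 5.14 CPM in hypoxia and 46.0 ± 2.92 CPM in normoxia, Eif2s3y at 36.2 ± 4.44 and 37.6 ± 1.29 CPM and Kdm5d at 21.6 ± 3.36 and 23.2 ± 3.61 CPM, and these were not called (edgeR adjusted p = 0.42, 0.75 and 0.66). Xist, a transcript of female cells, and the Y-linked genes were thus present together in both groups, far above their SDs. These levels argue against libraries made from cells of a single sex. The labels do not say whether mice were pooled.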
